A study of Homo sapiens with 24 samples.

How the data were processed

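RNA of human U-2 OS osteosarcoma cells was measured on 24 Agilent Human 1A v2 oligonucleotide arrays, each carrying 1 RNA labelled with Cy3 and 1 labelled with Cy5. Per the labels' protocols, cells received ethanol vehicle or 1 μM RU-486 for 6 h, 500 ng of total RNA was amplified linearly, 750 ng of each labelled cRNA was mixed, and hybridisation took 17 h. The arrays formed 12 dye-swapped pairs, 4 in each of 3 comparisons: RU-486 against vehicle in the line carrying hGRβ, RU-486 against vehicle in the line called U-OFF, and hGRβ against U-OFF RNA, both from vehicle-treated cells. The design text of the series describes 4 pairs of RNA per line as biological replicates from separate harvests. Replicate numbers follow the order of the records. Per the labels, the vehicle RNAs of the RU-486 arrays were also those on the arrays between the lines, where replicate 1 holds the vehicle RNAs of replicates 1 of both lines, and likewise for the others. Beyond that a number shared by the lines only names the pairs. The RNAs of the lines on such an array carry different dates in the labels. Each ratio between the lines therefore also holds the difference between harvests.

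The spot intensity values deposited for each array are mean pixel brightness and median local background per channel on a linear scale, not background-corrected, per the file headers. The authors extracted them with Agilent Feature Extraction 7.5 at default settings, per the submitters' processing notes. The deposited log10 ratio of each spot is the processed Cy5 signal over the processed Cy3 signal, spatially detrended and dye-normalised by that software, per the file headers. A further deposited table of the whole series holds log10 ratios. From 96.8% to 98.7% of its values per array lay within 1e-4 of the scanner software's log10 ratio after the sign had been turned by the authors on the arrays with RU-486 or hGRβ RNA in Cy3, and its array medians ran from -0.0028 to 0.0022. Spot flags for brightness over background, saturation and non-uniformity were used as deposited. The genome build and the positions of the probes are not given in the sources used here.

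Signals were background-corrected with normexp (offset 50) and normalised by loess within each array, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots marked as non-uniform were left out, spots of 1 probe were averaged, and each log2 ratio was turned to RU-486 over vehicle or hGRβ over U-OFF by the dyes in the labels. The 2 arrays of a pair hold the same RNAs and were averaged to 1 replicate. Tables and plots were prepared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. A probe was tested if it was well above background on all 8 arrays of at least 1 RNA in 1 comparison, which 18588 of 20173 gene probes were. A gene with several probes was represented by the brightest, giving 17466 genes. Gene names came from a RefSeq gene table (assembly GRCh38.p14), used for names and for the order of neighbouring genes. It named 6666 probes by accession, 6294 by symbol and 2181 by an older symbol, and 5032 kept the name in the files. The files describe 1459 probes as retired. Among the 1095 genes with several tested probes, 249 had a probe called between the lines and 1 had probes called in opposite directions.

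Array medians of the mean signal ran from 120 to 247 in Cy3 and from 198 to 370 in Cy5, over local backgrounds of 46 to 53 and 53 to 56. Of the gene spots, 92.4% in Cy3 and 94.9% in Cy5 were well above background, against 0.1% and 0% of those of the 162 negative control spots. The number of arrays limits the precision. The median standard error of a log2 ratio was 0.0289 for RU-486 and 0.0381 between the lines.

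The RU-486 ratios of both lines (8 replicates) were fitted together in limma with a mean per line, tested against 0 and against each other. The lines share 1 estimate of each gene's spread in that fit. A gene with values in every replicate therefore has the same RU-486 standard error in both lines, whatever each line's own spread. The ratios between the lines (4 replicates) were fitted alone. P-values were adjusted by Benjamini-Hochberg over all genes, and genes under 0.05 were called. The p-values between the lines measure the spread between harvests of 1 cell population of each line, not between independent clones. A probe saturated in all channels of 1 line gave a lower bound, from the means of normalised channel signals (loess, then Aquantile). In 18 gene lists fixed beforehand, called members were counted over all genes and adjusted over the list alone, and each list's members with values in every replicate were tested with camera at a preset correlation of 0.01 and with an estimated correlation. A second list test, fry, was run beside camera. The lists were glucocorticoid-induced, glucocorticoid-repressed inflammatory, interferon-stimulated, cell cycle, extracellular matrix, osteoblast, cholesterol biosynthesis, endoplasmic reticulum stress and amino acid response, xenobiotic response, steroid receptor machinery, p53 targets, hypoxia and glycolysis, immediate early, TGF-β and actin targets, and markers of epithelial, blood, endothelial and neural cells.

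Genes to be named were set by rule. Per comparison these were NR3C1, the 10 largest rises and 10 largest falls among called genes with 1 sign in all 4 replicates and both dye orientations, or the 10 smallest p-values where fewer than 10 passed. In each list they were up to 2 called members each way, or the 2 smallest p-values where none was called, plus TSC22D3, FKBP5, PER1, SGK1 and DUSP1. A few genes that the rule names, and 1 window of neighbouring genes, are not reported here. The design, lists, rule and most alternatives were fixed before the data were examined. The alternatives covered background correction, normalisation, the scanner's and the series table's ratios, scaling, the filter, saturated spots, probe choice, dye terms, single dye orientations, the samples in a fit, the prior variance, each replicate left out, the week of extraction, a replicate block and separate channels. Others were added later and are named as such. A dye effect was called in 11149 genes on the RU-486 arrays and 7974 on the arrays between the lines. After turning, the 2 arrays of a pair correlated over genes at 0.749 to 0.877 between the lines. In several RU-486 pairs they opposed each other, as given below. The week of extraction, read from the files, put 4 RU-486 pairs in week 1 and 4 in week 2, both lines in each, and all arrays between the lines in week 3.

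The procedure was tested on simulated data over 17099 genes, with 200 genes changed in each of 8 runs. These were split equally over changes of 1.25-, 1.5-, 2- and 4-fold, and the replicates' deviations were kept with their signs drawn anew. The larger changes ease the adjusted threshold for the smaller ones. The shares below therefore do not tell how many small changes were missed where no gene was called. For RU-486 in the hGRβ line, 80.8% of genes changed 1.25-fold and 94.2% of those changed 1.5-fold were recovered. For RU-486 in the U-OFF line the shares were 79.8% and 93.8%, and between the lines 53% and 68.8%, with 85.2% at 2-fold. The median number of calls among unchanged genes was 1, 0 and 0. With independent noise in place of the kept deviations it was 84.5, 10 and 10.5.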

Results

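Gene expression was measured in 2 populations of U-2 OS cells, a human osteosarcoma line, by competitive hybridisation of Cy3- and Cy5-labelled cRNA. The first carried hGRβ, a splice isoform of the human glucocorticoid receptor encoded by NR3C1, and the second, called U-OFF, served as its comparison line. Each was treated for 6 h with ethanol or with 1 μM RU-486 (mifepristone), an antagonist of the glucocorticoid and progesterone receptors. The series asked whether hGRβ regulates transcription and responds to a ligand. The 3 comparisons had 4 replicates each, a replicate being the mean of 2 dye-swapped arrays, and errors are standard errors from limma unless another is named.

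NR3C1, the gene whose isoform the first line is named for, had a log2 ratio of hGRβ over U-OFF cells of 0.14 ± 0.04 under vehicle (n = 4, limma adjusted p = 0.0816), above 0 in 4 of 4 replicates. With RU-486 its ratio was -0.17 ± 0.06 in hGRβ cells (adjusted p = 0.383) and 0.06 ± 0.06 in U-OFF cells (adjusted p = 1), with a difference of -0.23 ± 0.08 (adjusted p = 0.584). The part of the gene that the probe reads is not given in the sources used here, so it is open whether NR3C1 here stands for that isoform. The NR3C1 line ratio passed the threshold with median centring (0.22, adjusted p = 0.0295), unaveraged arrays with a dye term and the pair as a random block (0.14, adjusted p = 0.0342) and array weights (0.14, adjusted p = 0.0267), the last chosen after seeing the data. Over 21 other settings its adjusted p ran from 0.0267 to 0.634.

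RU-486 in hGRβ cells was followed by small shifts that did not pass the test for any gene. Among the 10 genes with the smallest p-values, 3 were clones without a gene name. The others included RANBP1, a regulator of the nuclear transport GTPase Ran, at 0.16 ± 0.02, KDELR3, a retrieval receptor of the endoplasmic reticulum, at 0.13 ± 0.02, and the ribosomal protein gene RPL7A at 0.18 ± 0.03. NNMT, nicotinamide N-methyltransferase, stood at 0.15 ± 0.02. On the other side were FUT8, a fucosyltransferase (-0.14 ± 0.02), DDX21, a nucleolar RNA helicase (-0.15 ± 0.02), and DNAJC3, a co-chaperone (-0.12 ± 0.02). FUT8 had a second probe at -0.12 ± 0.02. Each of these 7 genes had the same sign in 4 of 4 replicates and an adjusted p of 0.298. Over all genes the values ran from -0.79 to 0.48.

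**Figure D1:**
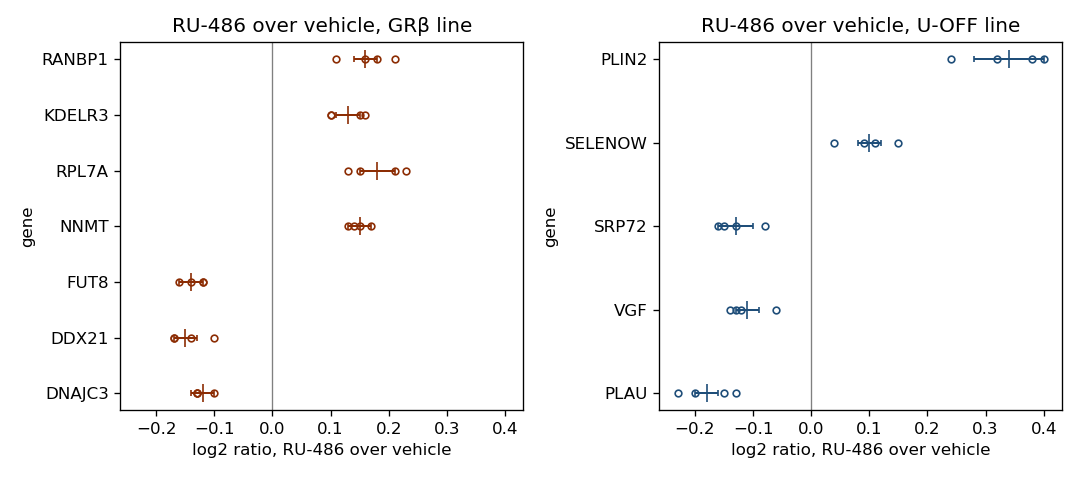
Log2 ratio of RU-486 over vehicle (horizontal axis) for genes with the smallest p-values, in hGRβ cells on the left and U-OFF cells on the right. Circles are the 4 replicates and bars the mean with its standard error, from a spread estimated over both lines. RANBP1 lies between 0.11 and 0.21 and PLIN2 between 0.24 and 0.40, and none of the genes drawn passed the test.

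Of the glucocorticoid-induced genes the smallest p-values in hGRβ cells after RU-486 belonged to BIRC3, an inhibitor of apoptosis, at -0.23 ± 0.07 (adjusted p = 0.346), and EDN1, endothelin 1, at -0.13 ± 0.04 (adjusted p = 0.341), both below 0 in 4 of 4 replicates. TSC22D3, which encodes the leucine zipper protein GILZ, was at 0.01 ± 0.02, the co-chaperone gene FKBP5 at 0 ± 0.02, the kinase gene SGK1 at -0.04 ± 0.03 and the phosphatase gene DUSP1 at -0.09 ± 0.03. The clock gene PER1 was at -0.01 ± 0.16, with replicates from -0.72 to 0.36. None of the 35 measured glucocorticoid-induced genes was called, and camera gave the list an adjusted p of 0.664.

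Lists shifted in hGRβ cells at the preset correlation although no member was called over all genes. The 38 immediate early genes, among them IER5 at -0.15 ± 0.04 and JUND at -0.08 ± 0.02 (0.1 ± 0.08 from its other probe), lay below other genes (camera adjusted p = 2.1e-05; adjusted p = 0.58 with an estimated correlation). The 46 cell cycle genes, with UBE2C at 0.13 ± 0.03 and the mitotic kinase gene PLK1 at 0.1 ± 0.02, lay above other genes (camera over 45 of them, adjusted p = 8.26e-05; adjusted p = 0.695 with an estimated correlation), and adjusted over the list alone 4 of them rose. The 29 glucocorticoid-repressed inflammatory genes lay lower (adjusted p = 0.00388; adjusted p = 0.695 with an estimated correlation), with the chemokine gene CXCL3 at -0.46 ± 0.14 and IL6 at -0.12 ± 0.04. The 28 p53 targets (adjusted p = 0.0228) and the 31 cholesterol biosynthesis genes (adjusted p = 0.0263) also lay lower, each with an adjusted p = 0.363 with an estimated correlation. ZMAT3 was at -0.14 ± 0.03 and PPM1D at -0.14 ± 0.04 among the former, NSDHL at -0.16 ± 0.04 and STARD4 at -0.12 ± 0.03 among the latter. The remaining 13 lists had adjusted p-values from 0.664 to 0.906, and adjusted over the list alone 1 interferon-stimulated gene rose and 1 endoplasmic reticulum stress gene fell. Their members nearest to the threshold included BST2 at 0.15 ± 0.03, the collagen gene COL4A2 at 0.12 ± 0.03, THBS1, thrombospondin, at 0.14 ± 0.03, TGFBI at -0.3 ± 0.08, BMP4 at 0.08 ± 0.02, PFKP of glycolysis at 0.11 ± 0.02 and the receptor cofactor gene NRIP1 at -0.18 ± 0.05. Markers of other cell types lay near 0 or varied, with KRT8 at 0.15 ± 0.05, CD53 at -0.12 ± 0.06, ENG at 0.02 ± 0.02 and CHGB at -0.15 ± 0.05. The osteoblast and blood cell tests pointed up beside means of -0.016 and -0.002, and the interferon, endoplasmic reticulum stress and xenobiotic tests pointed down beside medians of 0.006, 0.001 and 0.002. Within extraction week 1 none of the 5 lists passed (camera adjusted p from 0.303 to 0.991), and within week 2 all 5 did (from 8.65e-08 to 0.0338). Week 1 held hGRβ replicates 1 and 4 and week 2 held replicates 2 and 3. The week therefore cannot be told apart from replicate 2, which opposed the others over genes. Nor can it be told apart from U-OFF replicate 2, which was in week 1 and entered the spread shared by the lines. With median centring the cell cycle list did not pass (adjusted p = 0.435). The endoplasmic reticulum stress list then pointed down and passed (adjusted p = 0.000116). The p53 and cholesterol lists did not with the scanner's ratio (adjusted p = 0.0552 each).

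Of 17466 genes, limma called 0 in hGRβ cells, and 1890 had an unadjusted p under 0.05. Fitted on the replicates of this line alone, it called 0, with 1246 unadjusted. After turning, the 2 arrays of a pair correlated over genes at 0.486, 0.7, 0.38 and -0.563 in replicates 1 to 4. In replicate 4, what followed the dye thus outweighed what followed the RNA. The 72 genes that encode respiratory chain subunits, a group added after the data were seen, had a mean log2 ratio of 0.426 in replicate 2 against -0.204, -0.203 and -0.044 in replicates 1, 3 and 4. Over all genes replicate 2 correlated with replicates 1 and 3 at -0.43 and -0.41, while these correlated with each other at 0.94 (genes are not independent replicates). Unaveraged arrays with a dye term and the pair as a random block brought 55 calls. Array weights that nearly removed replicate 2 (weight 0.074) brought 10048, that group's mean as a covariate brought 989, and leaving out replicates 2 of both lines brought 4466. The last 3 were chosen after seeing the data. Leaving out replicate 2 of the hGRβ line alone gave 0 calls and 5063 unadjusted ones, and the fit within extraction weeks 1 and 2 gave 0 calls each, with 383 and 996 unadjusted.

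**Figure D2:**
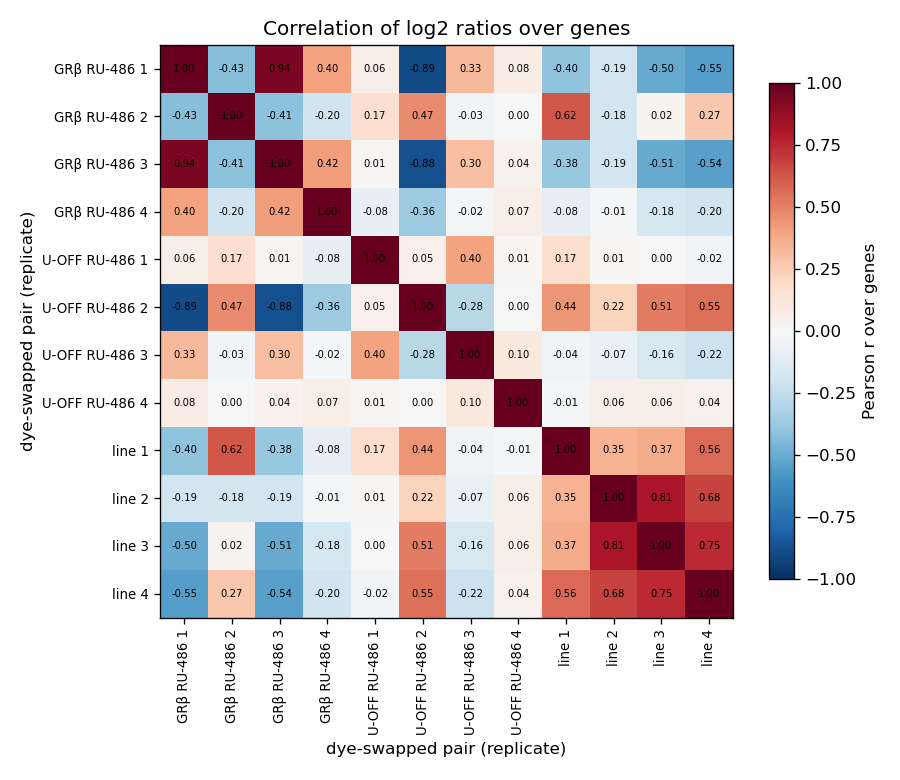
Pearson correlation over genes of the log2 ratios of the 12 dye-swapped pairs, with the pairs on both axes and colour from -1 to 1. Pairs 1 and 3 of RU-486 in hGRβ cells correlate at 0.94 with each other and at -0.89 and -0.88 with pair 2 of RU-486 in U-OFF cells, and the 4 pairs between the lines correlate at 0.35 to 0.81.

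RU-486 in U-OFF cells was likewise followed by no called gene. PLAU, the gene of the urokinase plasminogen activator, had the smallest p at -0.18 ± 0.02, and PLIN2, a lipid droplet coat protein, stood at 0.34 ± 0.06, both with 1 sign in 4 of 4 replicates and an adjusted p of 1. VGF, a secreted neuropeptide precursor, was at -0.11 ± 0.02 (-0.03 ± 0.14 from its other probe), SRP72, part of the signal recognition particle, at -0.13 ± 0.03 (0.02 ± 0.05 from its other probe) and the selenoprotein gene SELENOW at 0.1 ± 0.02. TSC22D3 (-0.03 ± 0.02), FKBP5 (0.03 ± 0.02), SGK1 (0.03 ± 0.03), DUSP1 (-0.03 ± 0.03) and PER1 (0 ± 0.16) lay near 0. None of the 571 measured list members was called, and adjusted over the list alone 1 glucocorticoid-repressed inflammatory gene fell. No list shifted as a whole, camera adjusted p-values running from 0.0618, for cell cycle genes, to 0.966. The cell cycle genes NEK2 and CDC20 were at -0.09 ± 0.03 and -0.11 ± 0.06, the cholesterol genes SREBF1 and DHCR7 at -0.1 ± 0.03 and -0.07 ± 0.03, the basement membrane collagen genes COL4A2 and COL4A1 at -0.07 ± 0.03 and -0.04 ± 0.01, and TNFRSF11B, osteoprotegerin, at -0.15 ± 0.04. The metallothionein gene MT1X was at 0.13 ± 0.05, the chemokine gene CCL20 at 0.21 ± 0.1, CALR, calreticulin, at 0.06 ± 0.02 and KRT18 at -0.1 ± 0.03. The endoplasmic reticulum stress, blood cell and neural tests pointed up beside means of -0.005, -0.003 and -0.002, and the p53 test pointed down beside a median of 0.003.

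limma called 0 of 17466 genes in U-OFF cells, and 233 had an unadjusted p under 0.05. Fitted on the replicates of this line alone, it called 0, with 433 unadjusted. The unadjusted counts of the lines thus differed less without the shared spread. After turning, the 2 arrays of a pair correlated over genes at -0.617, 0.45, -0.545 and -0.528 in replicates 1 to 4. In replicates 1, 3 and 4, what followed the dye thus outweighed what followed the RNA. Array weights, chosen after seeing the data, brought 2 calls, and single dye orientations brought 1046 and 790, in which a dye effect cannot cancel. With median centring the glucocorticoid-induced list (camera adjusted p = 0.0478) and the endoplasmic reticulum stress list (adjusted p = 0.00256) pointed up and passed in U-OFF cells. Cell cycle genes passed with the scanner's ratio (camera adjusted p = 0.0471), pointed up with median centring (adjusted p = 0.953) and did not pass within extraction weeks 1 and 2 (adjusted p = 0.669 and 0.0502).

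The test of whether the lines differed in their response to RU-486 also called 0 of 17466 genes with limma, and 1386 had an unadjusted p under 0.05. Of the named genes RANBP1 and KDELR3 had the smallest p-values, with differences (hGRβ minus U-OFF) of 0.21 ± 0.03 and 0.18 ± 0.03 and an adjusted p of 0.454 each. CXADR, the coxsackievirus and adenovirus receptor, was at 0.2 ± 0.03, RPL7A at 0.24 ± 0.04, NEO1 at 0.19 ± 0.03, GAS2L1 at 0.23 ± 0.04 (0.09 ± 0.04 from its other probe), SGCE at 0.16 ± 0.03 and BCAR3 at -0.12 ± 0.02, each with an adjusted p of 0.569. The largest values over all genes were -0.85 and 0.47. Cell cycle genes lay higher in hGRβ cells (camera over 45 genes, adjusted p = 6.25e-05; adjusted p = 0.756 with an estimated correlation), with NEK2 at 0.19 ± 0.04 and UBE2C at 0.16 ± 0.04. Immediate early genes lay lower (adjusted p = 0.00174; adjusted p = 0.756 with an estimated correlation), with KLF10 at -0.43 ± 0.12 and FOSL1 at -0.28 ± 0.1, though a second FOSL1 probe read -0.05 ± 0.03. Adjusted over the list alone, 1 inflammatory and 1 extracellular matrix gene were higher and 1 endoplasmic reticulum stress gene was lower. The other 16 lists had adjusted p-values from 0.144 to 0.992. Their members included PLAU at 0.18 ± 0.03, CCL20 at -0.51 ± 0.15, the collagen genes COL4A2 and COL6A1 at 0.2 ± 0.04 and 0.26 ± 0.06, RTP801 at 0.26 ± 0.09, TGFBI at -0.31 ± 0.11 and KRT8 at 0.25 ± 0.08. The osteoblast and steroid receptor tests pointed up beside means of -0.007 and -0.005, and the interferon, cholesterol, TGF-β and neural tests pointed down beside medians of 0.003 and 0.008 and means of 0.005 and 0.005. With median centring the cell cycle list lost its call (adjusted p = 0.583), and the endoplasmic reticulum stress (1.18e-05), p53 (0.00321) and cholesterol lists (0.00486) pointed down and passed. Within extraction week 1 both called lists lost their calls (camera adjusted p = 0.786 each). That week did not hold hGRβ replicate 2 but held U-OFF replicate 2, which stood apart from the other U-OFF replicates. The week can therefore not be told apart from either replicate. Within week 2 both passed (1.42e-11 and 3.56e-07) along with the inflammatory (0.0115, down), extracellular matrix (0.0142, up), endoplasmic reticulum stress and p53 lists (0.0368 each, down). Chosen after seeing the data, leaving out replicates 2 brought 7 called genes, array weights 6945 and the respiratory chain covariate 1.

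Between the lines under vehicle, 1802 of 17456 genes were called (10.3%), 1051 higher and 751 lower in hGRβ cells. A list with no tie to the lines would have about that share of its members called. Counts of called list members below are to be read beside it, and several, such as those of the steroid receptor and immediate early lists, lie near it. PTN, which encodes the growth factor pleiotrophin, was at least 28.9-fold higher (adjusted p = 5.35e-05), its probe being saturated on all 8 hGRβ channels and called retired in the files, while 2 other PTN probes read -0.21 ± 0.12 and -0.19 ± 0.11. HBG2, a fetal globin gene, rose by 4.71 ± 0.12 on the log2 scale (adjusted p = 0.00647), and its other probe by 0.18 ± 0.04. The acute-phase genes SAA1 (2.75 ± 0.44) and SAA2 (2.62 ± 0.48) were higher in 4 of 4 replicates, and a second SAA1 probe read 0.05 ± 0.03. DHRS2, a dehydrogenase gene, had the largest fall named, -2.47 ± 0.28, with -2.37 ± 0.25 from its other probe.

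MAOA, monoamine oxidase A, rose by 1.5 ± 0.11, and 1.45 ± 0.08 from its other probe. BEX1 (1.4 ± 0.21), the small GTPase gene RAC2 (1.29 ± 0.12), the chaperone genes HSPH1 (1.36 ± 0.16) and CRYAB (1.19 ± 0.21) and the cancer-testis antigen gene CT45A2 (1.36 ± 0.21) were also higher. Among the falls were TNFAIP2 (-1.8 ± 0.24), the bone morphogenetic protein gene BMP2 (-1.65 ± 0.11) and SEMA3A, an axon guidance gene (-1.61 ± 0.13; -1.17 ± 0.08 from its other probe). HHIP, the hedgehog-interacting protein (-1.54 ± 0.27), the cancer-testis antigen gene MAGEC1 (-1.46 ± 0.05), CDH2, N-cadherin (-1.39 ± 0.05), the scaffold gene AKAP12 (-1.31 ± 0.06) and NPC1, a lysosomal cholesterol transporter (-1.29 ± 0.14), fell as well. All of these had adjusted p-values from 0.0105 to 0.0465 apart from PTN and HBG2.

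**Figure D3:**
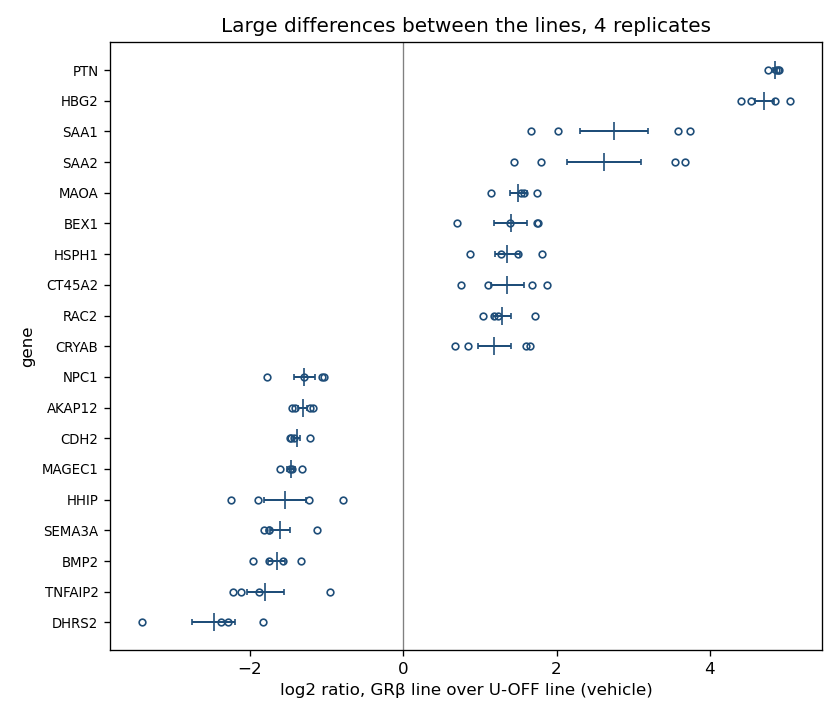
Log2 ratio of hGRβ over U-OFF cells under vehicle (horizontal axis) for the rises and falls named in the text from the largest set by rule. Circles are the 4 replicates and bars the mean with its standard error. The PTN probe, at 4.85, was saturated on all hGRβ channels.

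Cholesterol biosynthesis genes were higher as a group, with 11 of 31 rising, 0 falling and 20 not passing, and 15 rising adjusted over the list alone (camera over 28 genes, adjusted p = 8.68e-06; adjusted p = 0.699 with an estimated correlation). MVK, mevalonate kinase, rose by 0.82 ± 0.09 and SC5D, a sterol desaturase, by 0.71 ± 0.04 (n = 3). Interferon-stimulated genes were higher too, with 8 rising and 1 falling of 40, and 18 and 2 adjusted over the list alone (camera over 39 genes, adjusted p = 0.000163; adjusted p = 0.484 with an estimated correlation). SP110 rose by 0.58 ± 0.03 and the oligoadenylate synthetase gene OAS3 by 0.47 ± 0.05, while LGALS3BP fell by 0.31 ± 0.05. Of 30 genes of the steroid receptor machinery 3 rose and 1 fell, and 10 and 2 adjusted over the list alone (camera over 29 genes, adjusted p = 0.038; adjusted p = 0.484 with an estimated correlation), with the cochaperone gene TEBP at 0.74 ± 0.06, HSPA4 at 0.29 ± 0.02 and SMARCA4 at -0.22 ± 0.04. Of 38 immediate early genes 3 fell, also adjusted over the list alone (camera over 37 genes, adjusted p = 0.0392; adjusted p = 0.699 with an estimated correlation), including KLF6 (-0.59 ± 0.09) and JUND (-0.14 ± 0.02). With median centring that list lost its call (adjusted p = 0.495) and JUND read 0.10, while the other 3 lists kept theirs and the endoplasmic reticulum stress (adjusted p = 0.0132), hypoxia (adjusted p = 0.0208) and cell cycle lists (adjusted p = 0.0477) pointed up and passed.

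In the other 14 lists camera adjusted p-values ran from 0.0829 to 0.948. Of 33 TGF-β and actin targets 1 rose and 4 fell (2 and 6 adjusted over the list alone), with the receptor genes TGFBR1 at 0.14 ± 0.02 and TGFBR2 at -1.16 ± 0.13 (-0.38 ± 0.03 from its other probe) and INHBA at -1.27 ± 0.14. Of 46 extracellular matrix genes 1 rose and 5 fell (1 and 5), with COL16A1 at -0.55 ± 0.04, TNC at -0.75 ± 0.11 and COL15A1 at 0.13 ± 0.02. Of 35 osteoblast genes 2 fell, BMP2 and BMP6 (-0.54 ± 0.1), and 1 adjusted over the list alone. Of 35 endoplasmic reticulum stress and amino acid response genes 5 rose and 1 fell (6 and 2), with DNAJB9 at 0.53 ± 0.03, CANX at 0.52 ± 0.04 and PHGDH, of serine synthesis, at -0.89 ± 0.13; the list's median was -0.047 although its test pointed up. Of 31 hypoxia and glycolysis genes 4 rose and 1 fell (4 and 5), with PLOD2 at 0.75 ± 0.03 and the glucose transporter gene SLC2A1 at 0.4 ± 0.06. Of 22 xenobiotic response genes 3 rose and 1 fell (3 and 1), with the efflux pump gene ABCB1 at 0.95 ± 0.16, NQO1 at 0.43 ± 0.05 and ABCC3 at -0.47 ± 0.02, the test pointing down beside a mean of 0.031.

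Glucocorticoid-induced genes went both ways between the lines, with 2 rising and 2 falling of 35, the same counts adjusted over the list alone: MAOA and SLC19A2 (0.59 ± 0.09) rose, and GLUL, glutamine synthetase (-0.32 ± 0.04), was among those that fell. TSC22D3 (-0.02 ± 0.03), FKBP5 (-0.03 ± 0.02), PER1 (-0.03 ± 0.21), SGK1 (-0.03 ± 0.1) and DUSP1 (-0.28 ± 0.28) were not called. Of 29 glucocorticoid-repressed inflammatory genes LIF alone fell (-0.3 ± 0.06), and 0 adjusted over the list alone. Of 46 cell cycle genes 2 fell, thymidylate synthase, TYMS, at -1.15 ± 0.09 and CDC25A at -0.19 ± 0.03, and 1 adjusted over the list alone. Of 28 p53 targets 2 were called (4 adjusted over the list alone). XPC fell (-0.35 ± 0.07), while the probe of BBC3 was saturated in both lines, so that its call gives neither a fold nor a direction. Among markers of other cell types, HBG2 rose and 3 of 30 blood cell genes fell (1 and 3 adjusted over the list alone), among them CD3E (-0.14 ± 0.02) and CD79A (-0.28 ± 0.04); that list's test pointed down beside a mean of 0.156. Of 17 endothelial genes ERG rose (0.16 ± 0.02; its other probe read -0.03 ± 0.03), and of 19 neural genes STMN2 (-0.17 ± 0.03; -0.66 ± 0.07 from its other probe) and NEFM (-0.21 ± 0.04) fell (3 adjusted over the list alone). None of 26 epithelial genes was called, the smallest p belonging to KRT14 at -0.97 ± 0.23 (adjusted p = 0.0688).

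**Figure D4:**
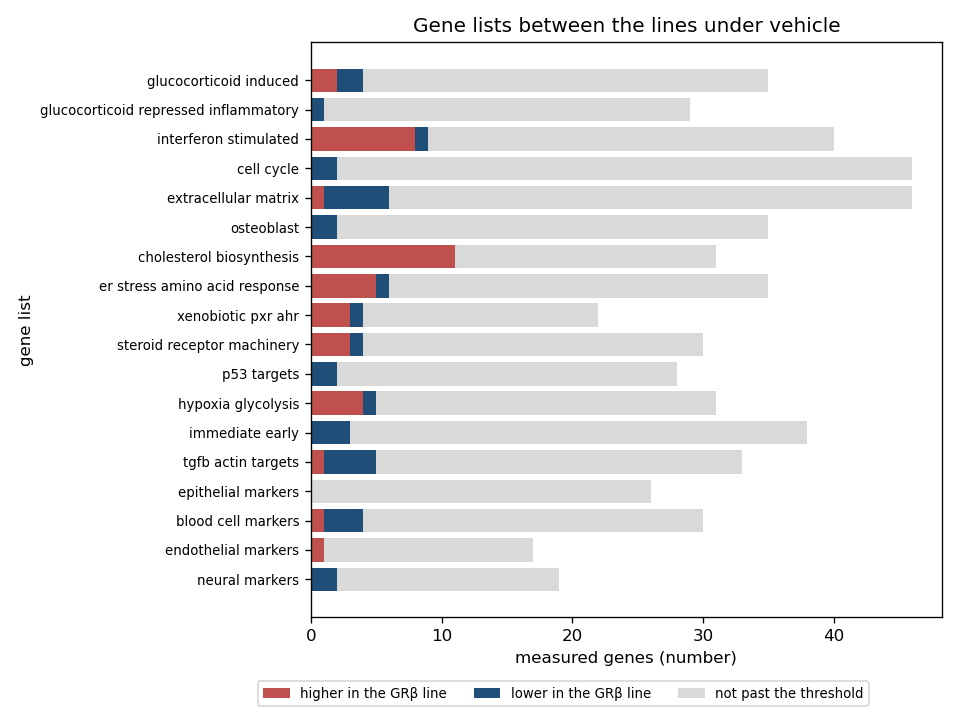
Number of measured genes (horizontal axis) in each of the 18 lists that were higher, lower or not past the threshold in hGRβ against U-OFF cells under vehicle. Cholesterol biosynthesis has 11 higher and 0 lower genes, and interferon-stimulated genes have 8 higher and 1 lower. Over all genes 10.3% were called.

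The called line differences had a median absolute log2 ratio of 0.345, with 337 at 1.5-fold or more, 54 at 2-fold or more and 7 at 4-fold or more. The count rested on the replicates: without replicate 3 limma called 1 gene, without replicate 4 it called 2, without replicate 2 it called 406 and without replicate 1 it called 2229. Unadjusted counts were 3786, 3584, 4679 and 6301. It was 3514 with median centring, 3992 with unaveraged arrays, a dye term and the pair as a random block, 3583 with hGRβ RNA in Cy5 only, 5589 with all replicates in 1 fit and, chosen after seeing the data, 4980 with array weights and 1 with the respiratory chain covariate. That covariate leaves fewer degrees of freedom and tests the ratio at a respiratory chain mean of 0, while the replicates lay at 0.09 to 0.596. With it 4186 genes had an unadjusted p under 0.05. The count of 1 therefore does not show that these genes account for the line differences. The vehicle RNAs read from separate channels of the RU-486 arrays called 1483 genes, 925 of them among the 1802, and 99.2% of the 1802 had the same sign there.

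The RU-486 ratios of the lines, which share no RNA, correlated over 17099 genes at r = -0.37 (covariance -0.00099), with 37.6% of genes of the same sign, and 0 genes were called in both. The negative sign came from U-OFF replicate 2, whose r with hGRβ replicates 1 to 4 was -0.89, 0.47, -0.88 and -0.36, while U-OFF replicates 1, 3 and 4 gave -0.08 to 0.33. In settings chosen after seeing the data, r was 0.24 without U-OFF replicate 2 (58.7% of the same sign) and 0.57 with it turned (69.9%). In others so chosen, r was 0.18 without replicates 2 of both lines (57.7%) and -0.71 without hGRβ replicate 2 alone (30.3%). The sign of this relation is therefore open. The line ratio shares vehicle RNA with each RU-486 ratio. It correlated with the hGRβ ratio at r = -0.31, against -0.35 simulated with no effect but the shared RNA (covariance -0.00481 against -0.00263). This r was -0.11 on average, from -0.41 to 0.37, where the RNA was split so that none was shared. Without hGRβ replicate 2, chosen after seeing the data, it was -0.49 (covariance -0.0105). With the U-OFF ratio r was 0.47 against 0.21 simulated (covariance 0.00434 against 0.000836), and 0.26 on average, from -0.1 to 0.56, when split. Without U-OFF replicate 2 it was -0.02, and with it turned -0.45, both chosen after seeing the data. Genes are not independent replicates, so no p is attached to these 3 relations.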

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

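The tests of an exchange in U-OFF pair 2, of dim probes and of unequal reading by probes were chosen after the results were seen. Among 174 groups of 4 values, 15 held a replicate far from the others by Dixon's ratio, where chance gives about 1 in 20.

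In U-OFF cells after RU-486, replicate 2 stood apart in the spread of log2 ratios (0.147 against 0.041 to 0.045, ratio 0.96), in the mean ratio of respiratory chain genes (0.273 against 0.001 to 0.044, ratio 0.84) and of ribosomal protein genes (0.193 against -0.003 to 0.028, ratio 0.84). It also stood apart for NR3C1 (0.25 against -0.02 to 0.02, ratio 0.86), KLF10 (0.48 against 0.02 to 0.09, ratio 0.85), FGFR3 (0.12 against 0.02 to 0.04, ratio 0.86), RTP801 (-0.33 against -0.09 to -0.05, ratio 0.83), UAP1 (-0.14 against -0.08 to -0.07, ratio 0.84) and XPC (-0.24 against -0.04 to -0.02, ratio 0.92). MX2 stood apart in replicate 4 (-0.06 against -0.01 to 0, ratio 0.89). In hGRβ cells it was UBE2C in replicate 2 (0.21 against 0.09 to 0.11, ratio 0.91) and NSDHL in replicate 4 (-0.07 against -0.2 to -0.18, ratio 0.88). Between the lines it was SEMA3A in replicate 4 (-1.13 against -1.81 to -1.75, ratio 0.91), ST14 in replicate 3 (-0.19 against -0.1 to -0.08, ratio 0.86) and ribosomal protein genes in replicate 1 (0.258 against -0.056 to -0.016, ratio 0.87).

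The effects of RU-486 in the lines differed, by the test of the difference itself, for cell cycle genes (camera adjusted p = 6.25e-05) and immediate early genes (adjusted p = 0.00174), and neither held with an estimated correlation (adjusted p = 0.756 each).

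The RU-486 ratios of hGRβ replicate 2 opposed those of replicates 1 and 3 over genes (r = -0.43 and -0.41), while replicates 1, 3 and 4 correlated with each other at 0.94, 0.4 and 0.41. An artefact of dye or single arrays is argued against only for the opposition of hGRβ pairs 1 and 3 to U-OFF pair 2. The 4 arrays of those hGRβ pairs, of both dye orientations, all correlated with U-OFF pair 2 at -0.6 or lower. That test used no array of hGRβ pair 2, whose 2 arrays correlated with each other at 0.7 after turning. A vehicle RNA standing apart stays open. By coefficients of the line arrays' deviation on the RU-486 ratio, 2 of 4 pairs showed what it predicts, hGRβ pairs 2 and 3 (-0.55 and -0.42). hGRβ pair 1 (-0.16) did not, and U-OFF pair 2 had the opposite sign (-0.26). That test cannot decide, because both ratios hold the same vehicle RNA, whose ordinary scatter moves the coefficient the predicted way. hGRβ pair 4, for which nothing was predicted, gave -0.44. An exchange of RU-486 and vehicle RNA, which would turn the sign of a pair, stays open too: for U-OFF pair 2, 33% of the 100 genes with the smallest p in the other 3 replicates had the same sign there, against 43.5% of all genes, between the bounds of 30% and 70% set for it after the pair's ratios had been seen. An exchange in hGRβ pair 2, and a response to RU-486 that differed between harvests, were not tested.

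Large line rises of PTN, HBG2 and SAA1 were read by 1 probe of several. Other probes with no signal over background are argued against for PTN and SAA1, as theirs were well above it on 8 of 8 channels of both lines. Most gene spots carried that flag, however, and these probes were dim, at log2 signals of 6.64 to 6.97. The bright probes read 15.65 in hGRβ and 10.79 in U-OFF cells for PTN, and 12.21 and 9.46 for SAA1. Whether the other probes were too dim to follow a rise therefore stays open. For HBG2 a lack of signal stays open too, its other probe being well above background on 8 of 8 hGRβ and 7 of 8 U-OFF channels. Unequal reading by probes of 1 gene in general stays open, since 4 of the 5 other genes called at 2-fold or more with several probes (80%) had another probe of the same sign with an unadjusted p under 0.05, too few genes to decide. A transcript made from a construct or a splice form that only 1 probe reads was not tested.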

How the results depend on the processing

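The alternatives with replicates 2 left out, the sign of hGRβ pair 2 turned, the respiratory chain covariate, array quality weights and retired probes left out were chosen after seeing the data, and the cause of the changes was not tested unless given here. RU-486 in hGRβ cells kept 0 called genes in 20 of 26 other settings. It had 55 (15 higher, 40 lower) from unaveraged arrays with a dye term and the pair as a random block, 2004 with RU-486 in Cy5 only and 2809 in Cy3 only, 4466 without replicates 2 of both lines, 989 with the respiratory chain covariate and 10048 with array weights. U-OFF cells kept 0 in 22 of 25 and had 1046 in Cy5 only, 790 in Cy3 only and 2 with array weights. Single orientations leave the dye effect in. The difference kept 0 in 27 of 30 and had 7 without replicates 2, 1 with the covariate and 6945 with array weights. Turning the sign of hGRβ pair 2, done because it opposed pairs 1 and 3, left 0 calls (5469 unadjusted, against 5063 without it), which says nothing on why it did. Leaving out each replicate left 0 calls in these 3 comparisons. Extraction week as a block left 0 (1872, 227 and 1378 unadjusted), as did week 1 (383, 430 and 1047) and week 2 (996, 52 and 414).

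The line count stayed within 1.5 times of 1802 in 12 of 21 settings. It was 3514 with median centring (1393 shared with the 1802), 3992 from unaveraged arrays with a dye term and the pair block (1718 shared), 3583 in Cy5 only (1648 shared), 5589 with all 12 replicates in 1 fit (1788 shared), 4980 with array weights (1796 shared) and 1 with the covariate. Without each replicate it ran from 1 to 2229, with fewer samples in the fit.

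Lists shifted numbered 5 in hGRβ cells, 0 in U-OFF cells, 2 for the difference and 4 between the lines. An estimated correlation left 0 for hGRβ cells, 0 for the difference and 0 between the lines. With fry no list passed in hGRβ cells (lowest adjusted p = 0.338), in U-OFF cells (0.187) or for the difference (0.235). Between the lines the interferon (fry adjusted p = 0.018) and steroid receptor lists (0.0119) passed, both up. The cholesterol (0.0938) and immediate early lists (0.204) did not. Median centring gave 5 in hGRβ cells, with the endoplasmic reticulum stress list in place of the cell cycle list, 2 in U-OFF cells, 4 for the difference and 6 between the lines. The scanner's ratio gave 3 in hGRβ cells and 1 in U-OFF cells. Week 1 left 0 in hGRβ cells and 0 for the difference, and week 2 gave 6 for the difference. The correlation of the line and hGRβ RU-486 ratios was -0.11 with the RNA split, against -0.31, and -0.49 without hGRβ replicate 2, chosen after seeing the data. In settings chosen after seeing the data, that of the 2 RU-486 ratios, -0.37, became 0.24 without U-OFF replicate 2 and 0.57 with it turned. It became 0.18 without replicates 2 of both lines and -0.71 without hGRβ replicate 2 alone, both so chosen. That of the line and U-OFF ratios, 0.47, became -0.02 without U-OFF replicate 2 and -0.45 with it turned, again so chosen.

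A replicate block, pairing harvests by number, left 0 called genes in the difference and moved the unadjusted count from 1386 to 3097. The labels give the lines different dates under each number, so the numbers were not taken to pair the harvests. Same-numbered deviations correlated at 0.57, 0.663, 0.682 and -0.108, and 2 of 4 hGRβ replicates correlated best with their own number.

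Among named genes, JUND between the lines read 0.10 with median centring, 0.13 in Cy5 only and 0.02 from separate channels against a fall. In Cy5 only it was called as a rise (limma adjusted p = 0.0498). PTN read -0.19 with retired probes left out against a rise. BBC3 read 0.41 in Cy3 only, from a probe saturated in both lines that gives neither a fold nor a reversal. Other named genes kept their sign where called: 268 values between the lines lost their call and 11 gained one, and 154 in hGRβ cells, 20 in U-OFF cells and 46 for the difference gained one. NR3C1 between the lines ran from 0.03 to 0.22. The filter on dim probes limited little, since 94.9% of gene spots in Cy5 were well above background.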

Other observations

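The test of a trend shared with the RU-486 ratios was chosen after the neighbour correlations had been seen, and the respiratory chain and ribosomal gene groups were added after seeing the data. The 72 respiratory chain genes had mean log2 ratios of hGRβ over U-OFF cells of 0.596, 0.09, 0.215 and 0.311 in the 4 replicates, above 0 in each, and in each too with median centring (0.798, 0.236, 0.401 and 0.565) and with the scanner's ratio (0.598, 0.075, 0.217 and 0.301). The 83 ribosomal protein genes had 0.258, -0.053, -0.056 and -0.016, and with median centring 0.627, 0.053, 0.255 and 0.311, so that replicates 2 to 4 changed sign with the scaling.

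Line differences were shared by neighbouring genes. In windows of 51 neighbours the median log2 ratio was 0.37 from ZNF24 to NARS1, 0.33 from MRPL39 to RCAN1, 0.27 from MSI1 to GTF2H3, -0.23 from USP14 to SNRPD1 and -0.22 from SMARCC1 to SEMA3B, where shuffled gene orders reached 0.13. These windows were picked for their medians. The first was the least steady, with 0.08, 0.5, 0.41 and 0.5 in the 4 replicates. Each of the others kept its sign in all replicates, running from 0.2 to 0.34 from MRPL39 to RCAN1 and from 0.17 to 0.33 from MSI1 to GTF2H3. The falls ran from -0.23 to -0.14 from USP14 to SNRPD1 and from -0.27 to -0.18 from SMARCC1 to SEMA3B. The medians of the RU-486 ratio in hGRβ cells over them were -0.09, -0.01, 0, -0.01 and 0.03.

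Related genes in tandem are argued against as the whole source, since ratios correlated at 0.081 even at 20 genes apart, where the highest of 1000 shuffled orders gave 0.032. A trend shared with the RU-486 ratios is argued against as the whole source by 0.087 after their removal (highest shuffled value 0.025). Copy number differences between the lines were expected to lift the correlation at 20 genes apart above the shuffled orders, and it lay there at 0.081. That expectation was not specific: the RU-486 ratio within hGRβ cells, where copy number cannot differ, gave 0.086. Copy number therefore stays open and would need DNA measurements, which were not analysed here.

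The 4 replicates gave 8 sign patterns, the labelled one among them, too few for a share under 0.05. Between the lines the labelled pattern gave 1802 calls and the highest other 0, so 1 pattern of 8, the labelled one itself, reached it. RU-486 in hGRβ cells and in U-OFF cells gave 0 under the labelled pattern and 0 under the highest other, in 8 of 8 with the labelled one counted. For the difference between the lines in RU-486 effect, the real split of the 8 replicates gave 0 calls and the highest of the others 0, and with 0 calls under the real split all 35 had to give as many, so the count decides nothing.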
